A study of Mus musculus with 12 samples.

How the data were processed

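Gene expression was measured in brain and liver of 10-week-old male BALB/c mice with Affymetrix whole-genome mouse arrays. Per the labels' protocols, fresh-frozen (FF) pieces were placed in RNAlater and their RNA was isolated with a column kit. Per the same protocols, formalin-fixed paraffin-embedded (FFPE) pieces were fixed for 24 h in 10% formalin, stored as blocks for 7 d at room temperature, and cut at 10 µm before RNA isolation. FF RNA was labelled with a 3' in vitro transcription kit, and FFPE RNA with a whole-transcript amplification kit made for FFPE material, per the labels' protocols. Preservation and labelling kit therefore always changed together, and so did time after death and storage temperature. The labels do not give the number of animals, or whether arrays share an animal.

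The deposited values are log2 intensities, 1 per probe set and array, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, sets the arrays on a common distribution and summarises probes. The notes do not say whether all arrays went through RMA in 1 run. Array medians were 4.65 to 4.68 in FF and 4.8 to 4.89 in FFPE, so the scale was not fully shared between the preservations. Deposited log2 values ran from 2.66 to 13.44. No depth exists for arrays, and the number of arrays limits the precision.

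From these values, 104 control probe sets were set aside. Of 45141 probe sets, 28898 were listed with 1 gene, 551 with several and 15588 with none, and symbols were taken from the reference tables. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 17097 genes. Genes at or above the array median in at least 3 arrays were kept, which left 13073 genes tested.

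Each of the 12 conditions had 1 array. Differences were estimated with limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The model for changes within a tissue held 4 series means (tissue by preservation) and the change at 3 h and 18 h in each tissue, 8 coefficients in all, with 4 residual degrees of freedom. In it a time effect is what the FF and FFPE arrays of a tissue share, from 2 arrays at each time. All 12 arrays shared 1 estimate of the spread per gene, so brain arrays also set the error of liver results and the reverse. A model with 6 coefficients and 6 residual degrees of freedom tested changes common to both tissues. FFPE was compared with FF, and liver with brain, from 3 arrays against 3, across the 3 times. P-values measure the spread between arrays and the disagreement between preservations, not the spread between animals. Pairs of single arrays were described by the number of genes differing at least 2-fold, with no p-value.

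Before the data were examined, 45 gene lists of pathways, complexes and cell types were fixed, of which 42 had the 4 measured members needed for a test. They were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. For single pairs of arrays, the list median was placed among 10000 random lists of the same size matched on expression. Of 137 list calls in the comparisons within and between tissues, 1 held with an estimated correlation, the Kupffer cell list in liver at 3 h. Genes named in the text follow a rule fixed at the same time. For each fitted comparison these are the 10 largest increases and 10 largest decreases among genes past the threshold that moved the same way in every pair of arrays. For each FF pair they are the 10 largest differences in each direction. From each list, up to 4 members past the threshold may be named, or up to 3 as values where none passed. Genes outside this rule are said to be so.

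The model was tested on simulated data for the 13073 genes with 200 changed genes. It recovered 76.5% and 70% of 2-fold changes at 3 h and 18 h in brain, 68.5% and 75.5% in liver, and 0% of 1.5-fold changes in these 4. For changes shared by both tissues it recovered 63% of 1.5-fold changes at 3 h and 63% at 18 h. The simulated spread was that of the model for changes within a tissue, which leaves out disagreement between tissues. The typical SD per gene was 0.1582 in that model and 0.1737 in the model for shared changes. Recovery of shared changes may therefore be overstated, and it cannot show that such changes were absent. For the tissue difference in the change the model recovered 27% of 2-fold changes at 3 h and 0% at 18 h. Of 4-fold changes it recovered 96.5% and 94.5%. Of 2-fold differences it recovered 82% and 86.5% for FFPE in brain and liver, 61.5% for their difference, and 83% and 84% for tissue in FF and FFPE. Each share came from a single random draw. The median SE of the tissue difference in the change was 0.221 at both times, so 27% and 0% show no difference between times. The adjusted threshold also depends on how many genes change. In the data 586 genes passed for that difference at 18 h, 375 of them at least 2-fold, and 1893 in liver at 18 h, 371 of them at least 2-fold. Alternatives were other filters, other ways to join probe sets, quantile normalization, centring of each array on its median, a mean-variance trend with robust estimation, subsets of arrays, and the omission of each array in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.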

Results

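The data comprised 12 arrays, 1 for each combination of 2 tissues (brain and liver), 2 preservations (FF and FFPE) and 3 times after death. Tissue was taken immediately after death (0 h), after 3 h at room temperature, or after 18 h at 4 °C. The design text gives the last condition as resembling the human autopsy process. No condition had a replicate, so every test below rests on differences shared by several conditions. Arrays of the same tissue and preservation correlated at 0.973 to 0.995 (Pearson r across probe sets, which are not independent replicates). FF and FFPE arrays of the same tissue and time correlated at 0.77 to 0.78 in brain and 0.842 to 0.883 in liver.

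The gap between 3' and 5' control probe sets was larger after death in FF liver than at 0 h. For Gapdh, a glycolytic housekeeping gene, the log2 gap between the 3' and 5' control probe sets in FF liver was 0.03 at 0 h, 0.82 at 3 h and 1.14 at 18 h. In FFPE liver the same gap was 1.04, 1.63 and 1.77. In brain it moved by at most 0.07 from its 0 h value in either preservation. For Actb, a cytoskeletal housekeeping gene, the gap in FF liver was 1.09, 2.00 and 1.90, whereas in FFPE liver it was -0.12, -0.01 and -0.18. In brain the Actb gap was 1.21, 1.21 and 1.32 in FF and -0.12, 0.05 and -0.10 in FFPE. These are single arrays with no replicate check, and the difference between tissues in the gap was not tested.

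**Figure D1:**
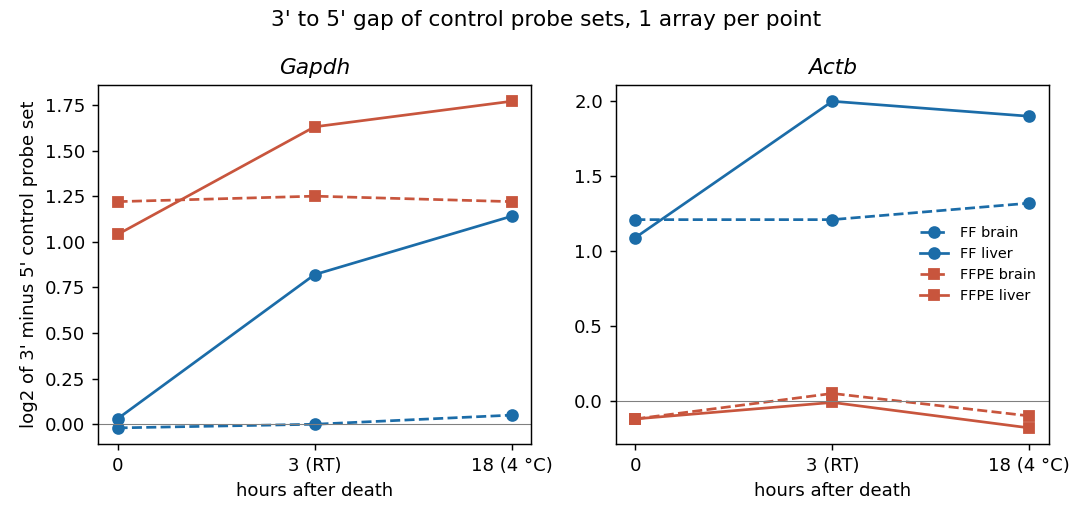
Difference in log2 signal between the 3' and 5' control probe sets of Gapdh and Actb (y axis) by hours after death (x axis, with storage at room temperature, RT, or 4 °C), 1 array per point. The Gapdh gap in FF liver went from 0.03 to 1.14, while the Gapdh gap in FF and FFPE brain stayed within 0.07 of its 0 h value and the Actb gap in brain moved by up to 0.17.

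Which transcripts changed with time after death in both tissues alike was asked first. In limma, 0 genes passed at 3 h and 0 at 18 h, from 4 arrays per time. At an unadjusted p under 0.05 there were 555 genes at 3 h and 1731 at 18 h, where 654 are expected if no gene changed, and the smallest adjusted p was 0.118 at 3 h and 0.311 at 18 h. Brain and liver changes were compared across genes, which are not independent replicates. Their Pearson r was 0.015 at 3 h and 0.035 at 18 h in FF, and 0.006 and -0.015 in FFPE. Within brain, FF and FFPE changes correlated at only 0.199 at 3 h and 0.185 at 18 h, and within liver at 0.297 and 0.473. The low r between tissues cannot show whether changes were shared, because each change rests on single arrays and r was low within brain too.

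In brain at 3 h, 6 genes rose and 4 fell, each with the same sign in FF and FFPE. Ttr, which encodes the thyroid hormone carrier made by choroid plexus and liver, rose by 5.40 ± 0.47 (log2 difference ± SE, 2 arrays per time, adjusted p = 0.00034). Its log2 level in FF brain was 8.68 at 0 h, 12.72 at 3 h and 12.21 at 18 h. Among the other increases were the kinase gene Prkcd (1.83 ± 0.20, adjusted p = 0.00294), the nuclear receptor gene Rora (1.06 ± 0.14, adjusted p = 0.0128), the vesicular glutamate transporter gene Slc17a6 (1.04 ± 0.16, adjusted p = 0.0288) and the dentate granule cell factor Prox1 (0.99 ± 0.14, adjusted p = 0.0238). The remaining increase was Plekhg1 (1.47 ± 0.16, adjusted p = 0.00278). Tac1, which encodes the substance P precursor and is abundant in striatum, fell by 1.13 ± 0.17 (adjusted p = 0.0288). The other decreases were the liver secretory genes Mup3 (-3.19 ± 0.17, adjusted p = 2.9e-06), Apoa1 (-1.75 ± 0.21, adjusted p = 0.00399) and Mup5 (-1.72 ± 0.25, adjusted p = 0.0238). Mup probe sets read a family of near-identical genes, so which member gave the signal is uncertain. Each time had 1 brain sample per preservation and the labels name no brain region, so a difference in the tissue sampled at 0 h cannot be separated from a change after death.

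At 18 h in brain, 4 genes passed, 1 higher and 3 lower. Ttr rose by 4.90 ± 0.47 (adjusted p = 0.00102), and Mup3 (-3.65 ± 0.17, adjusted p = 5.6e-07), Apoa1 (-1.74 ± 0.21, adjusted p = 0.00729) and Mup5 (-1.73 ± 0.25, adjusted p = 0.0425) fell. The comparisons at 3 h and 18 h share the 0 h arrays, and their results are therefore not independent. At an unadjusted p under 0.05 there were 684 genes at 3 h and 494 at 18 h, close to or below the 654 expected if no gene changed. With the 3 h arrays as the baseline, a choice made after seeing the data, 2 genes fell at 18 h and 0 rose.

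Groups of brain genes moved by smaller amounts. Of 8 measured choroid plexus and ependymal markers, 1 rose over all genes and 6 adjusted over the list alone at 3 h, with a list median of 0.86 (camera adjusted p = 3.2e-12, and 0.0657 with an estimated correlation). Of 14 oligodendrocyte markers, 0 passed over all genes and 8 were higher adjusted over the list alone, with a median of 0.51 (camera adjusted p = 3.2e-12, and 0.0657 with an estimated correlation). Their largest values were for the myelin genes Mag (0.79 ± 0.17) and Cldn11 (0.78 ± 0.15) and the lipid synthesis gene Ugt8a (0.69 ± 0.14). Striatal markers went the other way, with 1 of 8 lower over all genes, 3 adjusted over the list alone and a median of -0.29 (camera adjusted p = 2.3e-10, and 0.0657 with an estimated correlation). Excitatory neuron markers had 1 of 10 higher over all genes, 5 adjusted over the list alone and a median of 0.38, or 0.17 with the mean of probe sets (camera adjusted p = 1.6e-06, and 0.0657 with an estimated correlation). At 18 h the medians were 0.45 for choroid plexus, 0.27 for oligodendrocytes, -0.13 for striatum and 0.09 for excitatory neurons (camera adjusted p = 1.3e-05, 0.0002, 0.00227 and 0.0348, each 0.194 with an estimated correlation). The last was 0.0682 after quantile normalization. The striatal median at 18 h was -0.20 in FF and -0.05 in FFPE, and the excitatory median 0.17 in FF and 0 in FFPE, so both rested mostly on FF. Single genes high in choroid plexus also rose more in FF at 3 h, namely Kcnj13 (2.11 in FF, 0.44 in FFPE), Sostdc1 (2.10 and 0.59) and Folr1 (1.63 and 0.21). Ttr went the other way (4.04 and 6.75).

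Liver transcripts were present in the FF brain array at 0 h and much lower in the later FF brain arrays. Albumin (Alb) read 8.74 at 0 h, 6.11 at 3 h and 5.53 at 18 h, and Cyp3a11, a hepatic drug-metabolising enzyme, read 7.74, 4.60 and 4.11. In FFPE brain the differences of these genes from 0 h were smaller, at -0.54 and -0.51 for Alb and -0.27 and -0.38 for Cyp3a11. Mup3 went the other way, with -2.81 and -3.58 in FF and -3.56 and -3.73 in FFPE. Of 19 hepatocyte markers, 1 fell and 1 (Ttr, which is on this list too) rose over all genes at 3 h. Adjusted over the list alone 12 fell and 2 rose, with a median of -0.63 (camera adjusted p = 3.5e-12, and 0.273 with an estimated correlation). At 18 h 1 fell and 1 rose over all genes, 11 fell and 1 rose adjusted over the list alone, and the median was -0.57 (camera adjusted p = 2.2e-15, and 0.194 with an estimated correlation). In FF brain 74 genes differed at least 2-fold at 3 h (28 higher, 46 lower) and 49 at 18 h (7 higher, 42 lower). In FFPE brain the counts were 24 and 18. The order turned after quantile normalization, with 44 and 37 in FF and 62 and 48 in FFPE, and at 1.5-fold the FF split at 3 h was 174 higher and 159 lower. The decreases among the 10 largest in FF at 3 h were all abundant in liver, such as Serpina1c (-3.39 in FF, -0.95 in FFPE) and Car3 (-3.15 and -0.51). Serpina1 genes are near-identical paralogs and uncertain one by one. Across genes, which are not independent replicates, FF and FFPE changes in brain correlated at r = 0.199 at 3 h and 0.185 at 18 h. For unlike times r was 0.171 (FF 3 h with FFPE 18 h) and 0.133 (FF 18 h with FFPE 3 h), and each of these rests on the same 0 h arrays.

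**Figure D2:**
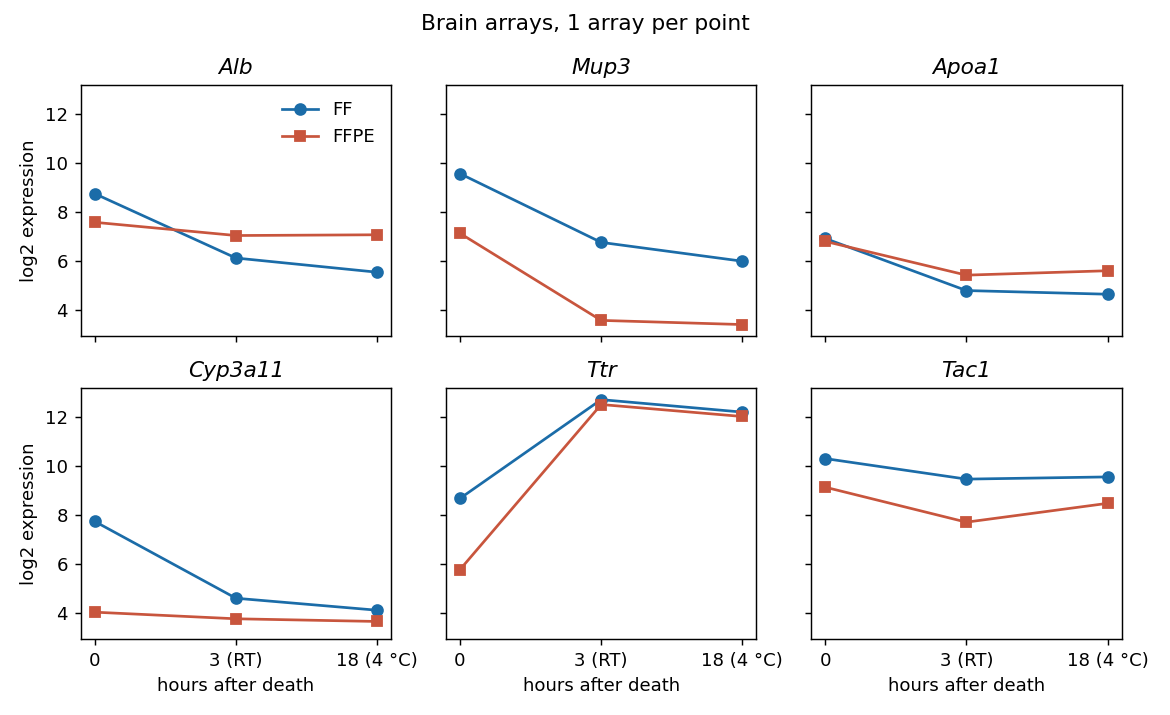
Log2 expression (y axis) of 6 genes in brain by hours after death (x axis), with FF in blue and FFPE in red, 1 array per point. Ttr was lowest at 0 h, whereas Alb in FF went from 8.74 at 0 h to 5.53 at 18 h.

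These brain counts rested on few arrays. At 3 h the count was 2 without the FF array at 0 h, 3 without the FF array at 3 h and 39 (8 higher, 31 lower) without the FFPE array at 0 h, and without the FFPE array at 3 h it was 8 (7 higher, 1 lower). At 18 h it was 31 (1 higher, 30 lower) without the FFPE array at 0 h, and 2 without the FF array at 0 h, the FF array at 18 h or the FFPE array at 18 h. The mean of all probe sets gave 4 genes at 3 h and 2 at 18 h, and ended the calls of Plekhg1 (0.91, adjusted p = 0.0993), Rora (0.41, adjusted p = 0.631), Prox1 (0.45, adjusted p = 0.711), Tac1 (-0.51, adjusted p = 0.453), Apoa1 (adjusted p = 0.0993 at 3 h and 0.228 at 18 h) and Mup5 (adjusted p = 0.0993 and 0.228). The differences of Apoa1 (-1.74 and -1.76) and Mup5 (-1.72 and -1.73) hardly moved with it. Mup5 at 18 h was also lost after quantile normalization (adjusted p = 0.0567). Robust estimation of the spread ended the call of Ttr (adjusted p = 0.245 at 3 h and 0.666 at 18 h), whose differences were 4.04 in FF and 6.75 in FFPE at 3 h. At 18 h the count was 2 with no filter and 2 with the 6 brain arrays alone. Without the 779 genes at least 4-fold higher in liver, a choice made after seeing the data, 6 genes passed at 3 h (5 higher, 1 lower) and 1 at 18 h.

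In liver at 3 h, genes of resident macrophages fell. Of 10 measured Kupffer cell markers, 5 fell over all genes, 9 fell adjusted over the list alone and 0 rose, with a median of -0.93. Vsig4, a complement receptor of Kupffer cells, fell by 1.91 ± 0.21 (2 arrays per time, adjusted p = 0.00323), with -1.50 in FF and -2.32 in FFPE. Cd5l, a secreted macrophage protein, fell by 1.46 ± 0.22 (adjusted p = 0.0176), and the lectin genes Fcna (-1.05 ± 0.15, adjusted p = 0.0142) and Clec4f (-1.02 ± 0.17, adjusted p = 0.0293) fell too. The genes of complement C1q, which macrophages make, also fell, with C1qc at -1.49 ± 0.18 (adjusted p = 0.00453), C1qb at -1.26 ± 0.20 (adjusted p = 0.0213) and C1qa at -1.20 ± 0.21 (adjusted p = 0.0458). The Kupffer cell list passed camera (adjusted p = 1.5e-17, and 0.0397 with an estimated correlation). Microglia markers in liver, a list that shares members with the Kupffer cell list, had 4 of 11 lower over all genes, 7 adjusted over the list alone and a median of -0.63 (camera adjusted p = 1.0e-08, and 0.158 with an estimated correlation). For 10 sinusoidal endothelial markers, 0 passed over all genes and 8 were lower adjusted over the list alone, with a median of -0.59 (camera adjusted p = 7.7e-10, and 0.312 with an estimated correlation). These markers moved beside a Gapdh gap that grew by 0.79 in FF liver and 0.59 in FFPE liver. The Actb gap grew by 0.91 in FF liver and 0.11 in FFPE liver.

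Among other liver genes at 3 h, the haemoglobin genes Hba-a1 (1.42 ± 0.20, adjusted p = 0.0127) and Hbb-b2 (1.30 ± 0.13, adjusted p = 0.00323) rose, 2 of 5 measured erythroid genes over all genes and 2 adjusted over the list alone (camera adjusted p = 0.012, and 0.426 with an estimated correlation). The median of the erythroid list was 0.09. In brain its median was 0.26 at 3 h and 0.25 at 18 h (camera adjusted p = 0.00328 and 0.000806 after quantile normalization). Both brain calls were lost with an estimated correlation. Haemoglobin genes are close paralogs, so the member is uncertain. Tfrc, the transferrin receptor gene, rose by 1.20 ± 0.14 (adjusted p = 0.00323), the transcriptional repressor gene Bcl6 by 1.45 ± 0.19 (adjusted p = 0.00981), Atxn1 by 1.34 ± 0.15 (adjusted p = 0.00323) and the clock gene Per2 by 0.87 ± 0.15 (adjusted p = 0.0293). Slco1a4, an organic anion transporter gene, rose by 1.15 ± 0.14 (adjusted p = 0.00453). Cirbp, which encodes a cold-inducible RNA-binding protein, fell by 1.26 ± 0.16 (adjusted p = 0.00648). The metabolic genes Csad for taurine synthesis (-1.33 ± 0.19, adjusted p = 0.0146) and Scd1 for fatty acid desaturation (-1.23 ± 0.19, adjusted p = 0.0238), and the glutathione transferase gene Gsta2 (-1.13 ± 0.16, adjusted p = 0.0135), fell as well.

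In total 32 genes passed at 3 h in liver (10 higher, 22 lower), each with the same sign in FF and FFPE, of which 21 differed at least 2-fold, and 1206 had an unadjusted p under 0.05. In FF liver 62 genes differed at least 2-fold (17 higher, 45 lower), and in FFPE liver 71 (33 higher, 38 lower). After quantile normalization these were 30 (10 higher, 20 lower) and 86 (48 higher, 38 lower). Both preservations shared 6 of the increases and 10 of the decreases, against 0.04 and 0.13 for independent sets. The count of 32 moved with the arrays used. It was 0 with the 6 liver arrays alone, 0 without the FFPE liver array at 3 h, 7 (4 higher, 3 lower) without the FFPE liver array at 0 h, and 83 (27 higher, 56 lower) without either liver array at 18 h. Without the FF liver array at 3 h it was 11 with 10 higher and 1 lower, so the excess of decreases did not hold there. Without the FF or the FFPE brain array it was 18 for 0 h, 14 for 3 h and 16 for 18 h. It was also 19 with no filter, 21 with the mean of all probe sets, 15 after quantile normalization, and 56 with every probe set tested on its own. The mean of probe sets ended the calls of Bcl6 (0.98, adjusted p = 0.138), Tfrc (0.50, adjusted p = 0.282) and Per2 (0.58, adjusted p = 0.0879). It also ended those of Cd5l (-1.46, adjusted p = 0.0539), C1qb (-1.26, adjusted p = 0.0516) and C1qa (-1.20, adjusted p = 0.0902), whose differences did not move. Quantile normalization ended those of Bcl6 (adjusted p = 0.0646), Per2 (adjusted p = 0.0646), Cd5l (adjusted p = 0.0651), Csad (adjusted p = 0.072), C1qb (adjusted p = 0.0513) and C1qa (adjusted p = 0.111).

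In liver at 18 h, 1893 genes passed, 14.5% of those tested, with 472 higher and 1421 lower. Among the 10 largest decreases, the serum amyloid genes Saa2 (-2.51 ± 0.13, 2 arrays per time, adjusted p = 2.2e-06) and Saa1 (-2.33 ± 0.16, adjusted p = 1.5e-05), and Apom, an apolipoprotein gene (-2.25 ± 0.15, adjusted p = 1.5e-05), fell in both preservations. Saa1 and Saa2 are close paralogs and may share probes. Commd3 (-2.25 ± 0.16, adjusted p = 2.0e-05) and Spcs1, a signal peptidase subunit gene (-2.01 ± 0.15, adjusted p = 2.7e-05), fell by similar amounts. Among the 10 largest increases were the matrix gene Efemp1 (1.35 ± 0.25, adjusted p = 0.00355), the growth factor-binding gene Igfbp3 (1.33 ± 0.30, adjusted p = 0.0111) and the collagen gene Col3a1 (1.25 ± 0.20, adjusted p = 0.00164). These 3 rose more in FF than in FFPE, with 2.03 and 0.68 for Efemp1, 2.17 and 0.49 for Igfbp3 and 1.76 and 0.74 for Col3a1. Ntn1, a guidance factor gene, rose by 1.26 ± 0.19 (adjusted p = 0.00116), with 1.23 to 1.29 in the pairs of arrays.

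Proteasome, respiratory chain and chaperone genes were lower in liver at 18 h, beside a Gapdh gap that had grown by 1.11 in FF and 0.73 in FFPE. The Actb gap had moved by 0.81 in FF and -0.06 in FFPE. Of 32 proteasome subunits, 17 fell over all genes, 25 fell adjusted over the list alone and 0 rose, with a median of -0.58 (camera adjusted p = 3.3e-11, and 0.47 with an estimated correlation). Psmb7 (-1.42 ± 0.14, adjusted p = 0.000107) and Psmd8 (-1.31 ± 0.14, adjusted p = 0.00018) are examples. Of 68 nuclear-encoded respiratory chain subunits, 26 fell and 1 rose over all genes, and 32 fell and 2 rose adjusted over the list alone, with a median of -0.40 (camera adjusted p = 5.4e-08, and 0.588 with an estimated correlation). The ATP synthase gene Atp5b fell by 1.38 ± 0.15 (adjusted p = 0.000195) and the cytochrome oxidase gene Cox5a by 0.96 ± 0.14 (adjusted p = 0.000902). Of 67 cytosolic ribosomal protein genes, 19 fell over all genes, 23 adjusted over the list alone and 0 rose, with a median of -0.25 (camera adjusted p = 0.000217, and 0.698 with an estimated correlation). Rplp0 fell by 1.12 ± 0.16 (adjusted p = 0.000746). Of 17 heat shock and chaperone genes, 8 fell over all genes and 9 adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.00241, and 0.491 with an estimated correlation), including Hsp90aa1 at -1.27 ± 0.22 (adjusted p = 0.00282). After quantile normalization the medians were -0.35 for the proteasome, -0.22 for the respiratory chain, -0.14 for ribosomal proteins and -0.28 for chaperones. Among random lists matched on expression, in FF and FFPE, the proteasome was at percentile 0.01 and 0, the respiratory chain at 0.86 and 2.53, and chaperones at 0.46 and 3.28. The ribosomal list was at percentile 6.93 in FF and 18.07 in FFPE, where random lists had a median of -0.31, so it was little lower than other genes of like expression. Chaperones had moved the other way in liver at 3 h, with a median of 0.07 in the model. Their medians there were 0.16 in FF and 0.26 in FFPE, at percentiles 98.94 and 100 of random lists. That call (camera adjusted p = 0.00155 after quantile normalization) was lost with an estimated correlation.

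Pericentral hepatocyte genes were also lower at 18 h. Of 14 pericentral hepatocyte genes, 6 fell over all genes and 6 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.000607, and 0.47 with an estimated correlation). Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, fell by 1.83 ± 0.18 (adjusted p = 0.000102), and Slc1a2, a glutamate transporter gene, by 1.54 ± 0.18 (adjusted p = 0.000283). Of 19 acute phase genes, 4 fell over all genes and 4 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0114, 0.542 with an estimated correlation, and 0.076 after quantile normalization, where the median was -0.13). It lay at percentile 11.3 in FF and 16.25 in FFPE among random lists. Crp, which encodes a pentraxin, fell by 0.78 ± 0.16 (adjusted p = 0.00643). Of 11 periportal genes 2 fell over all genes, and 2 fell and 1 rose adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.597). Of 18 genes of drug and bile acid metabolism 2 fell over all genes and 2 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.117). By contrast, 0 of 19 hepatocyte markers passed over all genes or adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.834).

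Stellate, sinusoidal endothelial and long noncoding RNA genes were higher in liver at 18 h, beside the same growth of the Gapdh gap (1.11 in FF, 0.73 in FFPE). The Actb gap had grown in FF alone (0.81, against -0.06 in FFPE). Of 11 stellate cell and fibroblast markers, 6 rose over all genes and 6 adjusted over the list alone, with a median of 0.57 (camera adjusted p = 1.4e-05, and 0.47 with an estimated correlation). Besides Col3a1 these included Ecm1 (1.10 ± 0.14, adjusted p = 0.000426), the secreted glycoprotein gene Reln (1.10 ± 0.15, adjusted p = 0.000519) and the proteoglycan gene Dcn (0.71 ± 0.14, adjusted p = 0.00427). Of 10 sinusoidal endothelial markers, 4 rose over all genes and 6 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.000159, and 0.491 with an estimated correlation), among them Bmp2 at 0.84 ± 0.17 (adjusted p = 0.00628). Of 14 long noncoding RNA genes, 5 rose over all genes and 6 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.00191, and 0.491 with an estimated correlation). Neat1, the scaffold of nuclear paraspeckles, rose by 0.98 ± 0.15 (adjusted p = 0.00102) and Malat1 by 0.59 ± 0.15 (adjusted p = 0.0223). Kupffer cell markers had 2 of 10 lower over all genes, 2 adjusted over the list alone and a median of -0.28 (camera adjusted p = 0.129).

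**Figure D3:**
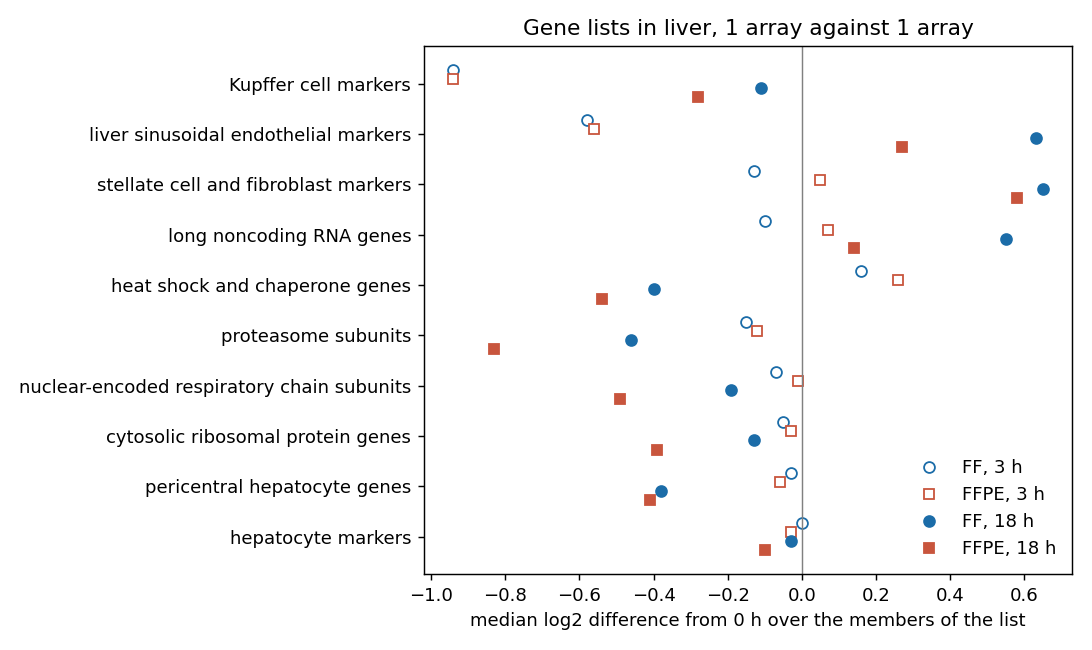
Median log2 difference from 0 h in liver (x axis) over the members of 10 gene lists (y axis), with circles for FF, squares for FFPE, open symbols for 3 h and filled symbols for 18 h, each from 1 array against 1 array. The Kupffer cell median was -0.94 at 3 h in both preservations, and -0.11 in FF and -0.28 in FFPE at 18 h.

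In FF liver 519 genes differed at least 2-fold at 18 h (160 higher, 359 lower), and in FFPE liver 618 (40 higher, 578 lower). The FFPE split was 103 higher and 417 lower after quantile normalization, and 13 higher and 411 lower with the mean of probe sets. Both preservations shared 12 increases and 141 decreases, against 0.49 and 15.87 for independent sets. Across genes, which are not independent replicates, the FF and FFPE changes correlated at r = 0.297 at 3 h and 0.473 at 18 h, and at 0.146 and 0.176 for unlike times. Fewer genes passed at 18 h with the 6 liver arrays alone (994, 166 higher and 828 lower), without the FF array at 0 h (1164, 151 higher and 1013 lower) or without the FFPE array at 0 h (1115, 323 higher and 792 lower). The split into directions also moved without the FF array at 18 h (309 higher, 1585 lower) and without the FFPE array at 18 h (761 higher, 1144 lower). Every probe set tested on its own gave 2947. The share of calls that were lower was 75.1%, and 63.4% after quantile normalization. With the mean of their probe sets, Ntn1 (0.49, adjusted p = 0.0572) and 2 others of the 10 largest increases, Trp53bp1 (0.37, adjusted p = 0.179) and Shroom3 (0.23, adjusted p = 0.158), were not past the threshold.

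**Figure D4:**
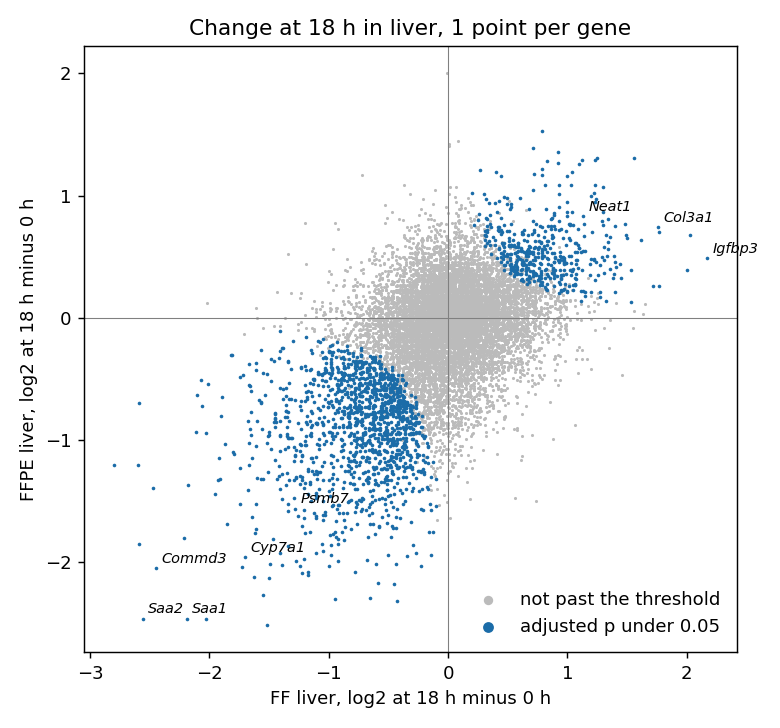
Log2 difference between 18 h and 0 h for each of 13073 genes in liver, FF on the x axis and FFPE on the y axis, 1 array against 1 array. Blue points passed the threshold in limma (472 higher, 1421 lower), and the decreases include Saa2 and Saa1.

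Whether time after death acted differently on liver and brain was tested as the difference between their changes. At 3 h, 2 genes passed. The liver change in Mup3 exceeded the brain change by 3.20 ± 0.24 (2 arrays per time and tissue, adjusted p = 0.000166), and in Ttr it lay below by -5.47 ± 0.66 (adjusted p = 0.0136), and both genes had passed in brain. At 18 h, 586 genes passed, 68 with a higher and 518 with a lower change in liver than in brain. The largest of either sign were Mup3 (3.62 ± 0.24, adjusted p = 3.9e-05) and Ttr (-4.93 ± 0.66, adjusted p = 0.00309). Mup3, Ttr, Serpina1b (2.19 ± 0.50, adjusted p = 0.0285), Fabp1 (2.10 ± 0.46, adjusted p = 0.0242) and Apoa1 (1.84 ± 0.29, adjusted p = 0.00653) moved in brain against its 0 h arrays and little in liver. Of these, Serpina1b (-3.32 in FF brain, -1.14 in FFPE brain) and Fabp1 (-3.08 and -1.22) had not passed in brain at 18 h. Saa2 (-2.42 ± 0.19, adjusted p = 0.000105), Saa1 (-2.43 ± 0.22, adjusted p = 0.000487) and Apom (-2.01 ± 0.21, adjusted p = 0.00171) were among the lower ones. Of 32 proteasome subunits, 11 had a lower change in liver over all genes and 19 adjusted over the list alone, with 0 higher and a median of -0.61, or -0.36 after quantile normalization (camera adjusted p = 4.1e-11, and 0.592 with an estimated correlation). Psmb7 differed by -1.40 ± 0.20 (adjusted p = 0.0039). Stellate cell and fibroblast markers had 3 of 11 higher over all genes, 5 adjusted over the list alone and a median of 0.56 (camera adjusted p = 1.9e-05, and 0.58 with an estimated correlation). For Kupffer cell markers at 3 h, 0 of 10 passed over all genes and 8 were lower adjusted over the list alone, with a median of -0.98 (camera adjusted p = 1.3e-10, and 0.103 with an estimated correlation).

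Single arrays moved these interaction counts strongly. The count of 586 was 48 without the FFPE brain array at 18 h, 74 without the FF brain array at 18 h, 96 without the FF brain array at 0 h, 113 without the FFPE brain array at 0 h, 390 without either brain array at 3 h, 376 without the FFPE liver array at 0 h, 946 (313 higher, 633 lower) without the FFPE liver array at 18 h and 1152 without the FF liver array at 18 h. It was 326 (81 higher, 245 lower) after quantile normalization and 1014 with every probe set tested on its own. The count of 2 at 3 h was 24 (19 higher, 5 lower) without the FFPE brain array at 0 h, 14 without either liver array at 18 h, 7 without the FF liver array at 0 h, 4 without the FFPE brain or the FF liver array at 3 h, and 1 without the FFPE liver array at 0 h or 3 h. It was also 1 with no filter, 5 after quantile normalization and 10 with every probe set. Robust estimation ended the call of Ttr (adjusted p = 0.461 at 3 h and 0.0804 at 18 h). The mean of probe sets ended those of Serpina1b (2.16, adjusted p = 0.0552) and Fabp1 (2.28, adjusted p = 0.0578) at 18 h.

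FFPE and FF values of the same tissue differed for most genes. In brain 10694 genes passed, 81.8% of those tested (3708 higher and 6986 lower in FFPE), and 6032 differed at least 2-fold. Bsn, a presynaptic scaffold gene, was higher in FFPE by 5.0 ± 0.16 (3 arrays against 3, adjusted p = 1.4e-10), and Selenow, a selenoprotein gene, by 4.27 ± 0.12 (adjusted p = 9.7e-11). The carboxypeptidase gene Scpep1 (-4.89 ± 0.19, adjusted p = 3.5e-10) and the stress transcription factor gene Xbp1 (-4.31 ± 0.23, adjusted p = 3.2e-09) were lower. In liver 9314 genes passed, 71.2% of those tested (3632 higher and 5682 lower), and 3545 differed at least 2-fold. Malat1, a nuclear noncoding RNA, was higher by 5.16 ± 0.13 (adjusted p = 1.8e-10), Selenow by 4.43 ± 0.12 (adjusted p = 2.2e-10) and the lipoprotein gene Apob by 3.71 ± 0.14 (adjusted p = 2.1e-09). Scpep1 was lower in liver too (-4.99 ± 0.19, adjusted p = 2.3e-09). Preservation and labelling kit cannot be told apart here. The direction shared by brain and liver covered 7271 genes (2571 higher, 4700 lower), and 799 genes passed in opposite directions.

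Housekeeping groups were lower in FFPE brain, where bright genes in general were lower too. Genes at or above the 75th percentile in at least 3 arrays had a median FFPE minus FF difference of -0.82 in brain. Of their calls 1844 were higher and 5680 lower. The lists were not placed among random lists of like expression here, so how far they exceed other bright genes was not tested. Of 68 respiratory chain subunits 57 were lower and 3 higher over all genes and adjusted over the list alone, with a median of -1.39, or -0.82 after quantile normalization (camera adjusted p = 0.000163, and 0.599 with an estimated correlation). Of 67 ribosomal protein genes 57 were lower and 1 higher by both counts, including adjusted over the list alone, with a median of -1.13, or -0.67 after quantile normalization (camera adjusted p = 0.000328, and 0.599 with an estimated correlation). Of 11 microglia markers 11 were lower over all genes and adjusted over the list alone, with a median of -1.23 (camera adjusted p = 0.0446, 0.438 with an estimated correlation, 0.105 after quantile normalization and 0.0571 with arrays centred on their medians). Hypothalamic and pituitary hormone genes, which liver does not make, had 8 of 10 higher and 1 lower in FFPE brain and 8 of 10 higher in FFPE liver, the same adjusted over the list alone. Their medians were 0.88 and 0.76 (camera adjusted p = 0.00949 and 0.0117, 0.438 and 0.756 with an estimated correlation, and 0.0976 and 0.0657 after quantile normalization). The median over all genes was -0.42 in brain and -0.17 in liver. It was -0.10 and -0.08 after quantile normalization, and -0.62 and -0.33 with arrays centred on their medians. The higher and lower calls were 4606 and 5540 in brain and 3989 and 4927 in liver after quantile normalization, and 2981 and 7796 in brain and 2760 and 6630 in liver after centring.

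Different probe sets of the same gene often disagreed between FFPE and FF. Among genes with at least 2 probe sets past the threshold in FFPE brain, 2057 of 3841 (53.6%) had probe sets past it in opposite directions, and 1701 of 3198 (53.2%) in FFPE liver. For liver against brain the share was 17.6% in FF and 9.7% in FFPE, and for liver at 18 h it was 11.4% (42 of 368). A direction given for a gene between FFPE and FF therefore holds for the probe set used. Every probe set tested on its own gave 17092 in brain and 14824 in liver.

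The FFPE minus FF difference differed between tissues for 7172 genes, 4760 higher and 2412 lower in liver than in brain. The contrast equals the FFPE minus FF difference in liver against brain, where the slope of FFPE on FF was 0.766. A narrower signal range in FFPE, or levels near background in 1 tissue, could give such calls and were not separated. Preservation and labelling kit cannot be told apart here either. Respiratory chain subunits had 56 of 68 higher over all genes and 57 adjusted over the list alone, with a median of 1.01, or 0.59 after quantile normalization (camera adjusted p = 2.6e-08, and 0.441 with an estimated correlation). Ribosomal protein genes had 49 of 67 higher over all genes, 52 adjusted over the list alone and a median of 0.88, or 0.50 after quantile normalization (camera adjusted p = 1.9e-06, and 0.465 with an estimated correlation). Sinusoidal endothelial markers had 9 of 10 lower over all genes and 9 adjusted over the list alone, with a median of -1.27, or -0.71 after quantile normalization (camera adjusted p = 2.9e-05, and 0.268 with an estimated correlation). Among single genes, Rims2, a synaptic release gene, differed by 4.61 ± 0.22 (3 arrays per group, adjusted p = 2.4e-08) and Slc3a1, an amino acid transporter subunit gene, by -4.99 ± 0.19 (adjusted p = 5.6e-09). Camk2a, a neuronal kinase gene, read 4.22 ± 0.26 but turned to -0.80 (adjusted p = 0.000652) with the mean of its probe sets. The share of calls that were higher was 66.4%, and 51.5% after quantile normalization, and every probe set tested on its own gave 11291.

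Liver and brain stayed clearly distinct in FFPE material. All 19 hepatocyte markers were higher in liver, over all genes and adjusted over the list alone, with medians of 7.08 in FF and 7.00 in FFPE (camera adjusted p = 1.5e-10 and 1.1e-11, and 0.187 and 0.206 with an estimated correlation). All 16 pan-neuronal markers were lower in liver by both counts, the one over all genes and the one adjusted over the list alone, with medians of -5.71 in FF and -4.53 in FFPE (camera adjusted p = 1.3e-09 and 1.1e-11, and 0.0629 and 0.0624 with an estimated correlation). The cytochrome P450 gene Cyp3a25 was higher in liver by 8.18 ± 0.16 in FF (3 arrays against 3, adjusted p = 8.6e-14) and 8.10 ± 0.16 in FFPE (adjusted p = 1.3e-13). Snap25, a synaptic vesicle fusion gene, was lower by -8.78 ± 0.11 (adjusted p = 4.1e-14) and -9.18 ± 0.11 (adjusted p = 2.4e-14). Snap25 in liver (3.25 to 3.42) and Cyp3a25 in brain (3.19 to 4.19) lay below the array medians, near the background, so these differences are lower bounds on their size. Respiratory chain subunits were higher in liver in FFPE for 57 of 68 over all genes and adjusted over the list alone, with 2 lower and a median of 0.98, or 0.54 after quantile normalization (camera adjusted p = 2.0e-08, and 0.392 with an estimated correlation). In FF 16 of 68 were higher and 10 lower, with 14 and 8 adjusted over the list alone and a median of 0.01 (camera adjusted p = 0.64).

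In FF 9685 genes passed between liver and brain (4778 higher, 4907 lower in liver), and in FFPE 8304 (4514 higher, 3790 lower). In FF the larger direction turned after quantile normalization (5397 higher, 4119 lower), with no filter (5854 and 5204) and with arrays centred on their medians (4895 and 4820). Of the 9685, 6399 (66.1%) passed in FFPE in the same direction, 457 in the opposite direction and 2829 did not pass. Of 2625 FF calls of at least 4-fold, 2551 passed in the same direction and 2 in the opposite. Across genes, which are not independent replicates, the tissue differences in FF and FFPE correlated at r = 0.867 at 0 h, 0.873 at 3 h and 0.878 at 18 h, and the slope of FFPE on FF was 0.766. Every probe set tested on its own gave 15072 in FF and 13218 in FFPE.

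**Figure D5:**
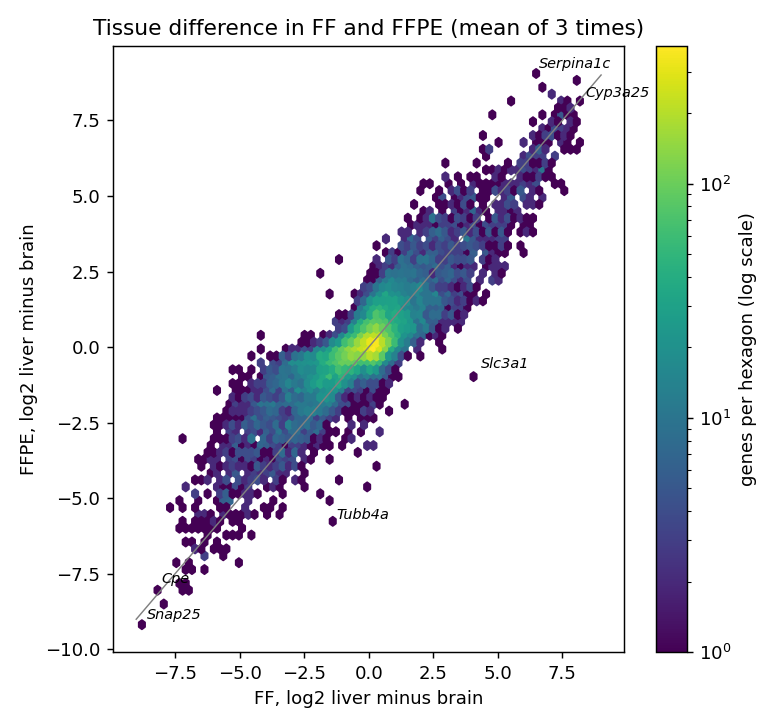
Log2 difference between liver and brain in FF (x axis) and in FFPE (y axis), mean of the 3 times, for 13073 genes, with colour for the number of genes per hexagon on a log scale. Most genes with large differences lie near the diagonal, and the slope of FFPE on FF was 0.766.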

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

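The tests of explanations and the splits of the arrays in this part were chosen after the result they measure was seen, except the test of RNA breakdown in liver at 18 h, while the interaction tests were planned.

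The brain arrays at 0 h held more liver transcript than the later brain arrays, although Ttr was lowest at 0 h and 8 of 19 hepatocyte markers were at or above the array median in the later FF brain arrays. Of the 100 genes most enriched in liver, chosen in FFPE, 88 were highest at 0 h in FF brain, against 30.8% of all genes. Their extra signal in FF brain was 0.327% of the liver signal (median, quartiles 0.145 and 0.63). For another set, the 100 genes chosen in FF, the extra signal in FFPE brain was 0.0455% (quartiles -0.0163 and 0.132). A loss after death in any tissue is argued against for the 100 genes chosen in FFPE. Their median change was 0 in FF liver at 3 h (quartiles -0.08 and 0.09), beside -0.56 in FF brain. A carry-over at FF labelling or arrays is argued against as the whole cause, since the hepatocyte list in FFPE brain (medians -0.20 and -0.27) lay at percentile 0 of random lists at 3 h and 18 h, and 53 of 100 genes chosen in FF were highest at 0 h in FFPE brain against 29.0% of all genes. Such a step stays open for the larger difference in FF (-0.99 at 3 h, FF minus FFPE), liver RNA carried into the 0 h material remains a candidate explanation, and no biological explanation was tested.

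Kupffer cell markers were lower in liver at 3 h and nearer to their 0 h level at 18 h. For 8 of 10 markers the level was higher at 18 h than at 3 h in both FF and FFPE. This argues against a loss that grows with time only if temperature and the piece taken made no difference. RNA breakdown stays open, because its members were higher at 18 h than at 3 h by a median of 0.76 in FF and 0.49 in FFPE while the controls went apart, with a Gapdh gap larger by 0.32 and 0.14 and an Actb gap that moved by -0.10 and -0.17. Fewer Kupffer cells in the piece or animal taken at 3 h stays open, since 9 of 10 markers were lower in both preservations and each condition had 1 array. Storage for 3 h was at room temperature and for 18 h at 4 °C, so an effect of temperature, which was not tested, stays open as well.

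More genes were lower than higher in liver at 18 h, with 75.1% of calls lower. Scaling of the arrays is argued against as the whole cause, since 63.4% of calls were lower after quantile normalization. The FFPE array alone stays open, since in the FF pair 69.2% of genes differing at least 2-fold were lower but 57% of those differing at least 1.5-fold, between the bounds of 55% and 60% set for that test. RNA breakdown stays open too. The 578 genes at least 2-fold lower in FFPE liver at 18 h had at 3 h in FF 22.2% of their 18 h change (medians -0.14 and -0.63). The change in the Gapdh gap at 3 h in FF liver was 71.2% of that at 18 h. The Actb gap went otherwise, with changes of 0.91 at 3 h and 0.81 at 18 h in FF liver and 0.11 and -0.06 in FFPE liver. The 95% interval of the 22.2% was 20 to 26.2 over 2000 bootstrap draws of genes and reached the bound of 25% set for that test. Genes are not independent replicates and both changes share the FF array at 0 h, so the interval does not measure the spread between arrays. Storage temperature and the piece or animal taken cannot be told apart from time after death, and no biological explanation was tested.

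A difference between groups drew attention to 3 results, each tested as an interaction. Liver and brain differed in their change for 2 genes at 3 h and 586 genes at 18 h, and in their FFPE minus FF difference for 7172 genes. Signal outside the comparisons drew attention to 2 further values. The 18S rRNA control probe sets were 1.53 log2 higher in FFPE (12.53 to 12.69) than in FF (10.83 to 11.58), and of 8899 probe sets without a single listed gene, 1052 passed in liver at 18 h (613 higher, 439 lower).

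For the difference between tissues in FFPE minus FF, splits of the arrays also say nothing about chance, because splits that mix FF and FFPE arrays put the large preservation effect into the spread. The real value was 7172, reached by 1 of 100 splits, and the highest other was 6278, among 18 splits that kept the real grouping in 1 tissue, while the 81 others gave 0. For the change shared by both tissues the splits say nothing about chance. The real count was 0 in limma (555 and 1731 genes at an unadjusted p under 0.05), so 100 of 100 relabelings gave as many at each time by construction (highest other 0 at 3 h and 1 at 18 h). Comparisons of 3 arrays with 3 had 10 splits each, too few for a share under 0.05. The real values were 10694 for FFPE in brain, 9314 for FFPE in liver, 9685 for tissue in FF and 8304 for tissue in FFPE, and the highest other was 0 in each. Every other split mixed FF with FFPE arrays, or liver with brain arrays, and put that large effect into the spread. These counts of 0 therefore say nothing about chance.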

How the results depend on the processing

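The alternatives with the 3 h arrays as baseline, without the 0 h brain or 18 h liver arrays, and without genes enriched in liver were chosen after seeing the data. Centring each array on its median kept 176 of 176 named genes of the fitted comparisons past the threshold in the same direction, a mean-variance trend with robust estimation 172, quantile normalization 166 and the mean of probe sets 155. In the last, Camk2a turned to -0.80 in the tissue difference of FFPE minus FF. Of 137 list calls, 136 were lost with an estimated correlation and 34 after quantile normalization. Counts that moved more than 1.5-fold follow, and the cause was not tested unless the number of genes or arrays is given as the reason. With no filter, and so more genes tested, counts were 2 in brain at 18 h, 19 in liver at 3 h and 1 for the tissue difference at 3 h. The mean of probe sets gave 4 and 2 in brain at 3 h and 18 h and 21 in liver at 3 h, and 13, 10 and 47 genes at least 2-fold different in FFPE brain at 3 h and 18 h and FFPE liver at 3 h. Quantile normalization gave 15 in liver at 3 h, 5 and 326 for the tissue differences at 3 h and 18 h, and 2-fold counts of 44 in FF brain and 30 in FF liver at 3 h, and 62 and 48 in FFPE brain at 3 h and 18 h. Testing every probe set, and so 20789 features, gave 56 and 2947 in liver at 3 h and 18 h, 10 and 1014 for the tissue differences, 17092, 14824 and 11291 for FFPE in brain, in liver and between them, and 15072 and 13218 for tissue in FF and FFPE. The 6 arrays of a tissue alone, fewer arrays, gave 2 in brain at 18 h and 0 and 994 in liver at 3 h and 18 h. With the 3 h baseline brain at 18 h gave 2, and without genes enriched in liver brain gave 6 and 1. A looser bound of 1.5-fold gave 333, 227, 508 and 2171 genes in FF (brain at 3 h and 18 h, then liver) and 300, 273, 568 and 2100 in FFPE, and a stricter bound of 4-fold gave 17, 15, 0 and 21 in FF and 2, 2, 3 and 26 in FFPE. Leaving out each array in turn, where a lone array was assumed to vary like the others, gave 0 to 0 for both tissues together at 3 h and 18 h in limma (555 and 1731 genes at an unadjusted p under 0.05 with all arrays), 2 to 39 and 2 to 31 in brain at 3 h and 18 h, 0 to 83 and 1115 to 1905 in liver, 1 to 24 and 48 to 1152 for the tissue differences, 9977 to 11007, 8443 to 9141 and 6115 to 7614 for FFPE in brain, in liver and between them, and 8677 to 10086 and 7326 to 8777 for tissue in FF and FFPE. No call changed direction in these. The number of arrays limited precision, with a median SE of 0.156 log2 for changes over time.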

Other observations

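No test here was chosen after its result was seen, and the gene lists are those named in the methods. In brain at 3 h, 0 immediate early, heat shock or hypoxia-inducible genes passed over all genes in limma, where 684 genes had an unadjusted p under 0.05. Of 31 immediate early genes 4 were higher adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.0024, and 0.14 with an estimated correlation). Arc, a synaptic plasticity gene, read 0.75 ± 0.16 (adjusted p = 0.212) and Fos, a transcription factor gene, 0.70 ± 0.16 (adjusted p = 0.29). Of 17 heat shock and chaperone genes 1 was higher adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0012, and 0.273 with an estimated correlation), and the small chaperone gene Cryab read 0.91 ± 0.19 (adjusted p = 0.18). Of 22 hypoxia-inducible genes 0 passed adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.81). At 18 h in brain, 0 of 11 microglia markers passed over all genes and 2 were higher adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.00405, 0.194 with an estimated correlation, and 0.0682 after quantile normalization).

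In liver at 18 h, single genes of the clock, of apoptosis and of lipid synthesis passed, those named here with the same sign in FF and FFPE. Of 17 circadian clock genes 1 rose and 1 fell, the same adjusted over the list alone (median 0.04, camera adjusted p = 0.254), and so did 1 and 1 of 15 apoptosis regulators (median 0.05, camera adjusted p = 0.715). Per2, a clock gene, rose by 1.09 ± 0.15 (adjusted p = 0.000595) and the clock-related repressor gene Nfil3 fell by 0.67 ± 0.15 (adjusted p = 0.00946). The pro-apoptotic gene Bcl2l11 rose by 1.14 ± 0.17 (adjusted p = 0.000952), while the anti-apoptotic gene Mcl1 fell by 0.71 ± 0.15 (adjusted p = 0.00712). The fatty acid synthesis genes Fasn and Acaca rose, with Fasn at 0.93 ± 0.14 (adjusted p = 0.00119) and Acaca at 0.77 ± 0.14 (adjusted p = 0.00382), and the cholesterol synthesis genes Fdps (-0.99 ± 0.18, adjusted p = 0.00298) and Msmo1 (-0.96 ± 0.14, adjusted p = 0.00112) fell. That list had 3 of 21 higher and 6 lower, the same adjusted over the list alone (median -0.05, camera adjusted p = 0.989). Of 22 hypoxia-inducible genes 6 fell, the same adjusted over the list alone (median -0.17, camera adjusted p = 0.145), including the glycolytic gene Pgk1 at -1.33 ± 0.14 (adjusted p = 0.00018). Of 19 unfolded protein and integrated stress response genes 6 fell over all genes, and 6 fell and 2 rose adjusted over the list alone (median -0.09, camera adjusted p = 0.187), including the chaperone cofactor gene Sdf2l1 at -1.46 ± 0.19 (adjusted p = 0.000404).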
